A study of Mus musculus with 2 samples.

How the data were processed

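Total RNA sequencing of whole liver from mouse embryos at embryonic day 15.5 was analysed in 2 libraries, which are biological replicates of 1 group per the labels. The labels give RNA longer than 200 nt, an input of 10 ng and added spike-ins. Each library came with a table of genes and a table of transcripts. Per the companion descriptions, both were made on the mm10 assembly with annotation M4. The column names are those that RSEM writes. The aligner, the quantifier and their versions are not given in the sources used here. The deposited expected counts are the authors' estimates of reads or fragments per gene and per transcript, without scaling and with spike-ins included. The deposited TPM and posterior mean TPM are the authors' abundances normalised for transcript length and library total, with spike-ins included in the total. Deposited effective lengths were mostly 99 nt below the lengths, which inflates the TPM of very short features.

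The gene tables held 43346 genes, 97 spike-in entries and 26248 entries with a numeric identifier, whose nature the labels do not state. The numeric entries were left out of all comparisons, since they held almost no counts. TPM was rescaled after spike-ins were left out. Symbols, biotypes and coordinates came from GENCODE M21 on the same assembly (GRCm38), a later annotation than M4. It named 42462 of the genes, and the other 884 kept their identifiers. A gene was detected at 1 TPM or more in both libraries. Values are the mean and SD over the 2 libraries. A count of 0 was taken to allow up to 3 counts of the library total. Counting intervals and this limit cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Depth was 34039441 and 44200863 expected counts without spike-ins in replicates 1 and 2.

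Before the data were examined, 40 lists with 492 symbols were fixed for liver functions, blood lineages, supporting cells, neighbouring organs, cell division, histones and stress. They held 470 distinct measured genes, and 4 symbols were not matched. Lists for exocrine pancreas, skeletal muscle and eosinophils were added after the values were seen and are used in the closing part of the text alone. The genes named were set by a rule fixed before the data were examined: in each list the 4 highest members, the lowest and the one with the largest difference between libraries, the 20 highest genes of all, and the 8 genes most in excess in each library. The latter had at least 10 TPM and at least 50 expected counts in either library, with pseudogenes left out. The rule for transcripts took 7 preset genes and the 10 highest list genes in which the leading 2 transcripts each held at least 20%. Not every gene the rule gives is printed, and some are not reported here.

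Replicate 2 was compared with replicate 1 as the log2 ratio of TPM + 1. Genes with 5 TPM or more in either library were counted when they differed by more than 2-fold. The exact 95% interval of the count ratio (Clopper-Pearson, scaled by library totals) was computed for each gene. With 1 library on each side no p-value is given. A list with at least 5 members at a mean of 1 TPM or more was placed by the percentile of its median log2 ratio among 10000 random lists of the same size, matched on expression in 50 bins. A list stood apart below the 2.5 or above the 97.5 percentile. Sampling noise between the libraries was tested by the chi-square of rounded counts over genes with at least 10 counts. The leading transcript was taken by TPM in genes at 5 TPM or more in both libraries.

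Alternatives were other detection limits, a pseudocount of 0.1, no filter on low values, TMM scaling (edgeR 4.0.16), median-of-ratios scaling (DESeq2 1.42.0), spike-in scaling, expected counts in place of TPM, posterior mean TPM, removal of trends with length or GC content by medians in 40 bins, and each library alone. Some of these were chosen after the data were seen. The 2-fold interval rule and the list test were tested on simulated data. Of 50 genes with a true 3-fold difference 45 were found, of 50 with a 1.5-fold difference 0, and of 12599 unchanged genes 0. These genes all had a simulated mean of at least 50 counts in the smaller library before any change. No reads were divided among copies. The rates for genes therefore do not cover genes with fewer counts or with shared reads. Of 100 lists shifted by 0.3 on the log2 scale 99 stood apart, as did 4 of 100 unchanged lists. Simulated genes varied independently, while members of a real list can vary together, so these rates need not hold for the real lists. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and R 4.3.3.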

Results

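Messenger RNA and other transcripts longer than 200 nt were measured in whole liver of mouse embryos of the B6NCrl strain at embryonic day 15.5, when the liver is both a forming metabolic organ and the main site of blood cell production. The 2 libraries were biological replicates of a single group. Replicate 1 came from the pooled livers of 78 embryos and replicate 2 from those of 62 embryos, with both sexes in each pool. Each library was made from 10 ng of RNA with synthetic spike-in RNAs added. The deposited tables held 34820426 expected counts for replicate 1 and 45117192 for replicate 2, spike-ins included. The design held no treated, mutant or control group, so the comparisons it implies are of genes and gene groups within the tissue and of replicate 2 against replicate 1. Levels are given as TPM, a measure of abundance corrected for transcript length, with spike-ins left out, as mean ± SD over the 2 libraries (n = 2) unless a single library is named. Gene groups are the sums of TPM over lists fixed before the data were examined.

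At 1 TPM or more in both libraries, 12331 genes were detected, of which 11403 are annotated as protein-coding and 119 as long intergenic noncoding RNAs. A single library detected 12698.5 ± 60.1 genes (SD, n = 2). Protein-coding genes held 93.0% ± 0.104 (SD, n = 2) of all TPM. The RNA was dominated by few genes: the 10 highest genes took 44.0% of TPM in replicate 1 and 44.0% in replicate 2, and the 100 highest took 58.9% and 59.0%. Apart from the globins, the protein-coding nuclear genes among the 20 highest encode plasma proteins of hepatocytes, ferritin chains, an antioxidant enzyme, a metallothionein and a histone.

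Red cell genes were the most abundant RNAs of the tissue. The 25 measured erythroid genes held 39.2% ± 0.557 of TPM (SD, n = 2), nearly all of it from the 4 adult globin genes, which held 38.5% ± 0.594. Hba-a2 (ENSMUSG00000069917; chromosome 11, 32296489 to 32297298, GRCm38), an adult alpha globin gene, was the highest gene at 162412 ± 509.6 TPM, and its neighbour Hba-a1 (chromosome 11, 32283511 to 32284465) reached 70239 ± 1287 TPM. The adult beta globin genes Hbb-bs (ENSMUSG00000052305; chromosome 7, 103826534 to 103828096) and Hbb-bt (chromosome 7, 103812524 to 103813996) stood at 80748 ± 3703 and 71429.9 ± 3010.3 TPM. All 25 genes lay above 10 TPM in both libraries and 21 above 100 TPM. Klf1, an erythroid transcription factor, stood at 451 ± 59.5 TPM, and the lowest member, the blood-forming transcription factor Tal1, at 26.6 ± 2.95 TPM. Without the 4 adult globins the remaining erythroid genes summed to 0.714 ± 0.0366% of TPM (SD, n = 2). The split of reads between Hba-a1 and Hba-a2, and between Hbb-bs and Hbb-bt, is uncertain because each pair is nearly identical in sequence. The share also depends on length correction: the same genes held 19.5% of expected counts, in which long transcripts weigh more.

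The enzymes of heme synthesis were abundant throughout the pathway. The 9 genes summed to 5002 ± 188 TPM (SD, n = 2), and 8 of them exceeded 100 TPM in both libraries. Alas2, the erythroid form of the first enzyme, reached 1374 ± 113 TPM, and Fech and Alad reached 599 ± 21.6 and 542 ± 4.66 TPM. Alas1, the form of the first enzyme used by other tissues, was the lowest of the group at 29.8 ± 1.95 TPM. The Alas2 to Alas1 ratio was 46.3 ± 6.82 (SD, n = 2), so the difference far exceeded the spread between the libraries.

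Embryonic globins were present at a small level. Hbb-y, the embryonic beta-like gene, stood at 372 ± 148 TPM, Hbb-bh1 at 50.5 ± 12.9 TPM and Hba-x, the embryonic alpha-like gene, at 85.0 ± 24.3 TPM (SD, n = 2). Together, Hbb-y and Hbb-bh1 made up 0.275 ± 0.0929% of beta-like globin TPM, and Hba-x made up 0.0366 ± 0.0106% of alpha-like globin TPM. Each of the 3 genes was higher in replicate 2, Hbb-y by 1.78-fold (268 against 477 TPM). The SD of the embryonic shares is therefore large beside their means. The ratio of alpha-like to beta-like globin TPM was 1.53 ± 0.0737 (SD, n = 2).

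Hepatocyte genes formed the next largest group. The 25 hepatoblast and hepatocyte genes held 5.05% ± 0.734 of TPM (SD, n = 2), with 5.57% in replicate 1 and 4.53% in replicate 2. Trf, which encodes the plasma iron carrier transferrin (ENSMUSG00000032554; chromosome 9, 103204001 to 103230444), led with 12785 ± 3462 TPM. Afp, the fetal serum protein alpha-fetoprotein (chromosome 5, 90490737 to 90508907), reached 10876 ± 739 TPM, Apoa2 reached 6069 ± 113 TPM and Alb, the gene of serum albumin (chromosome 5, 90460897 to 90476602), reached 5192 ± 898 TPM. Afp exceeded Alb in both libraries, with a ratio of 2.11 ± 0.223 (SD, n = 2). The fetuin gene Ahsg stood at 3135 ± 950.0 TPM. Foxa1, a transcription factor of the liver program, was the lowest member at 1.23 ± 0.237 TPM, and all 25 members were at 1 TPM or more in both libraries. The erythroid list exceeded the hepatocyte list by 2.96 ± 0.231 on the log2 scale (SD, n = 2), or 7.85 ± 1.25-fold. An exact two-sided sign test over 2 libraries cannot go below p = 0.5, so the comparison rests on its size relative to the spread. This order depends on the globins: without the 4 adult globins in one list and Alb, Afp and Apoa1 in the other, the log2 ratio was -2.03, with a hepatocyte share of 2.93%. Without the 4 highest genes of each list, an alternative chosen after the data were seen, it was -1.12, with a hepatocyte share of 1.56%, and by expected counts with all genes it was 1.44.

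Genes for proteins that the liver secretes were broadly active at this stage. The 13 genes of lipoprotein assembly summed to 17728 ± 1318 TPM (SD, n = 2), led by Apoa2, Apoa1 at 5130.1 ± 584 TPM, Apoe at 2854 ± 508 TPM and Apoc2 at 1192 ± 120.1 TPM, while Apoa4 stood at 0.310 ± 0.000765 TPM. The 15 coagulation genes summed to 4535 ± 650.2 TPM, with 9 above 100 TPM in both libraries. Fga, a fibrinogen chain, was at 949.5 ± 139 TPM, Serpinc1, the gene of antithrombin, at 920.4 ± 105 TPM, and F9, coagulation factor IX, was the lowest at 3.12 ± 0.00692 TPM. The 15 complement genes summed to 1238 ± 201 TPM, from C3 at 394 ± 66.5 TPM and Cfb at 304 ± 61.1 TPM down to C6 at 2.64 ± 0.131 TPM. The 15 genes of iron handling summed to 23079.8 ± 3623 TPM, of which transferrin and the ferritin chains Ftl1, at 5889 ± 318 TPM, and Fth1, at 3586 ± 275 TPM, were the most abundant. Hpx, the gene of the heme carrier hemopexin, stood at 348 ± 38.0 TPM, and Hamp2 was the lowest at 0.0932 and 0 TPM in replicates 1 and 2.

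Metabolic genes of the liver were uneven. The 6 urea cycle genes were all above 10 TPM in both libraries and summed to 461 ± 93.6 TPM (SD, n = 2), with Ass1 at 256 ± 58.9 TPM, Arg1 at 66.8 ± 18.5 TPM and Cps1, the entry enzyme of the cycle, at 20.6 ± 9.68 TPM. Of 10 genes of gluconeogenesis and amino acid breakdown, 4 lay above 10 TPM in both libraries, among them Hpd at 70.0 ± 17.4 TPM, Fbp1 at 62.9 ± 32.8 TPM and Pcx at 59.8 ± 14.6 TPM. Tdo2, which opens tryptophan breakdown, stood at 0.0104 and 0.0310 TPM in replicates 1 and 2. Of 12 cytochrome P450 genes, 5 reached 1 TPM in both libraries. Cyp3a11 was the highest at 30.1 ± 1.04 TPM, followed by Cyp8b1, an enzyme of bile acid synthesis, at 6.44 ± 3.40 TPM, while Cyp2c29 had a count of 0 in both libraries, which allows up to 0.0881 and 0.0679 counts scaled to a library total of 1e6. Of 7 transporters of bile acids and drugs, 5 reached 1 TPM, among them Abcb4 at 22.0 ± 1.58 TPM and Slc10a1, the bile acid uptake transporter, at 15.8 ± 5.82 TPM. Slco1a1 stood at 0.0104 and 0.0206 TPM in replicates 1 and 2.

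Other blood lineages were present at lower levels than the erythroid genes. The 14 granulocyte and monocyte genes summed to 6515 ± 276 TPM (SD, n = 2), led by S100a8 and S100a9, the genes of calprotectin, at 2549 ± 361 and 1397 ± 17.3 TPM, by the lysozyme gene Lyz2 at 663 ± 48.1 TPM and by Ngp at 482 ± 62.7 TPM. The 12 megakaryocyte and platelet genes summed to 524 ± 0.909 TPM, mostly from the platelet chemokines Pf4 at 243 ± 14.1 TPM and Ppbp at 134 ± 4.20 TPM. The 15 macrophage genes summed to 691 ± 71.6 TPM, with Hmox1, which breaks down heme, at 145 ± 11.8 TPM, the complement component C1qb at 113 ± 16.4 TPM and Cd163 lowest at 0.212 ± 0.0517 TPM. Stem and progenitor genes summed to 98.2 ± 2.63 TPM over 16 genes, with Spi1 at 24.5 ± 0.660 TPM, the receptor gene Kit at 11.2 ± 0.232 TPM and Hoxa9 at 0.30 ± 0.131 TPM. The 6 mast cell and basophil genes summed to 19.5 ± 0.932 TPM, with Hdc, the gene of the histamine-forming enzyme, at 7.02 ± 0.348 TPM. Of 12 B lymphoid genes, 7 reached 1 TPM in both libraries. The highest were Igll1, at 11.6 ± 2.52 TPM, and Cd79b, at 8.11 ± 1.46 TPM, which act in the receptor of early B cells. Of 9 T and NK lymphoid genes, 1 did so, the kinase gene Lck at 2.62 ± 0.571 TPM, and Cd3e had a count of 0 in both libraries.

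Vessel and supporting cell genes were present at lower levels than the erythroid and hepatocyte genes. All 16 endothelial genes lay at 1 TPM or more and summed to 191 ± 19 TPM (SD, n = 2), with Eng at 24.5 ± 3.94 TPM, the scavenger receptor gene Stab1 at 23.7 ± 3.77 TPM, Lyve1 at 21.7 ± 0.646 TPM and Emcn lowest at 1.70 ± 0.107 TPM. The 16 stellate and mesenchymal genes summed to 361 ± 10.8 TPM, led by the collagen genes Col3a1 at 101 ± 1.64 TPM and Col1a1 at 71.6 ± 1.23 TPM. Mesothelial genes summed to 13.0 ± 0.714 TPM over 6 genes, with Upk3b at 4.96 ± 0.405 TPM, and bile duct genes to 25.3 ± 10.8 TPM over 9 genes, with Spp1, the osteopontin gene, at 12 ± 7.49 TPM and Krt19 at 3.63 ± 0.433 TPM. Among the lists for neighbouring organs, 13 heart and skeletal muscle genes summed to 294 ± 89.1 TPM, with the muscle actin genes Acta1 at 122 ± 36.0 TPM and Actc1 at 74.2 ± 22.6 TPM. The 10 pancreas genes summed to 52.1 and 8.28 TPM in replicates 1 and 2. Summed TPM of the gut and stomach list was 13.9 ± 0.180, of the neuron list 4.16 ± 0.911, of the adrenal and gonad list 2.44 ± 0.540, of the lung list 0.439 ± 0.0209 and of the kidney list 0.315 ± 0.0227 (SD, n = 2). A list gives the level of marker RNA in a mixed tissue and no share of cells.

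**Figure D1:**
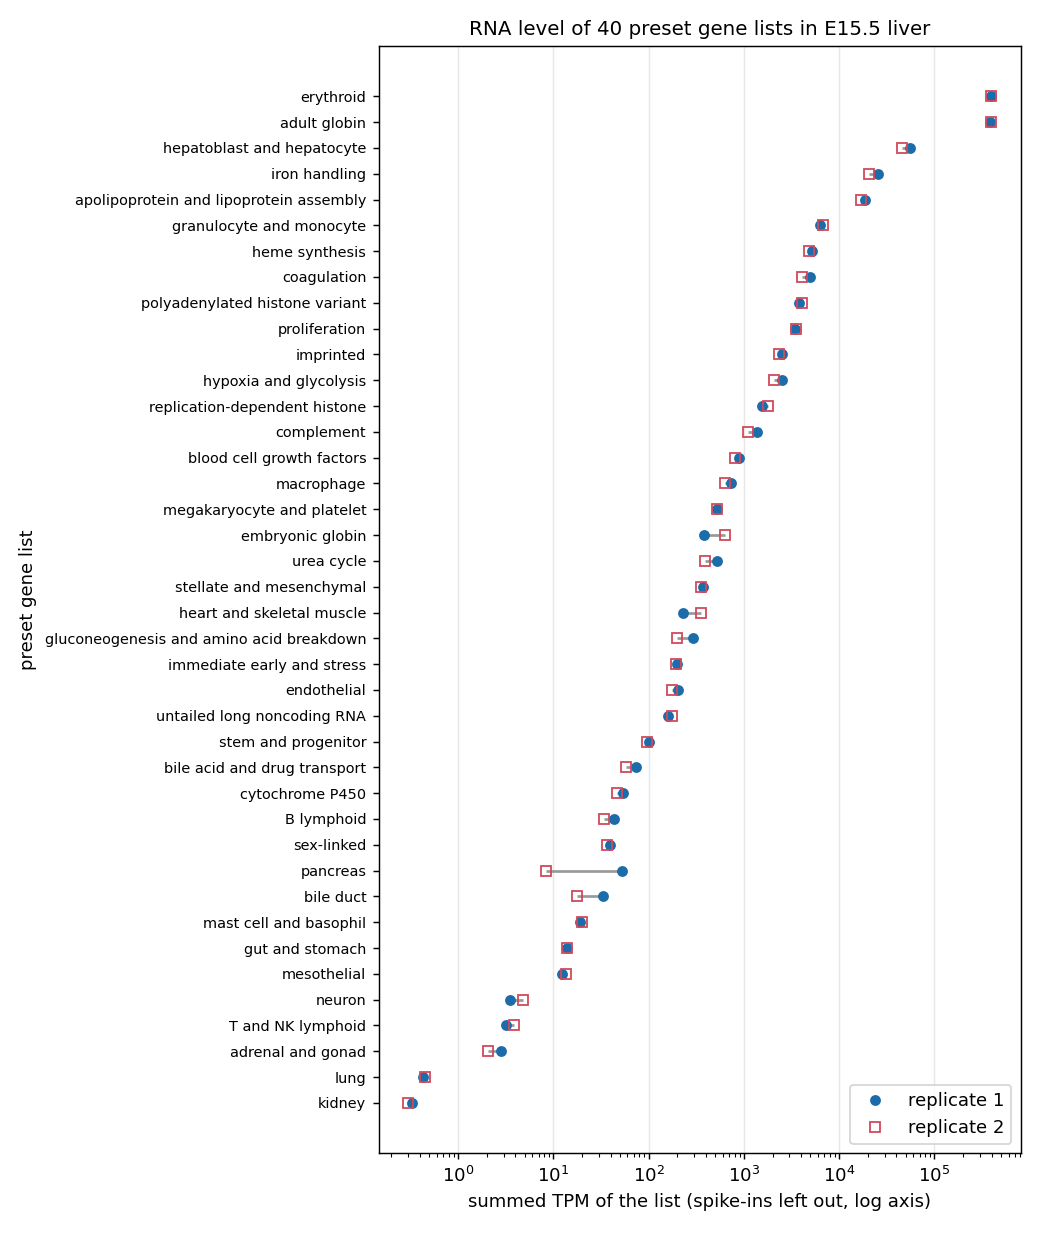
Summed TPM of 40 preset gene lists on a log axis, with a filled circle for replicate 1, an open square for replicate 2 and a grey line between them. Values run from 0.315 ± 0.0227 TPM for the kidney list to 391970 ± 5570.0 TPM for the erythroid list, and the widest gap between the libraries is that of the pancreas list, 52.1 and 8.28 TPM.

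Cell division genes were widely active. The 21 proliferation genes summed to 3484 ± 58.0 TPM (SD, n = 2), all of them above 10 TPM and 16 above 100 TPM in both libraries. Rrm2, a subunit of ribonucleotide reductase, reached 423 ± 15.8 TPM, Birc5 302 ± 26.9 TPM, Cdk1 275 ± 7.43 TPM and Pcna 242 ± 16.5 TPM, and the transcription factor Foxm1 was the lowest at 14.9 ± 0.0806 TPM. Imprinted genes summed to 2433 ± 152 TPM over 18 genes, with the fetal growth factor gene Igf2 at 604 ± 44.3 TPM, the noncoding RNA H19 at 504 ± 62.2 TPM, Dlk1 at 428 ± 2.59 TPM and Meg3 at 244 ± 19.4 TPM, against 0.936 ± 0.170 TPM for Kcnq1ot1. The 12 growth factors for blood cells summed to 841 ± 60.8 TPM, mostly Igf2. Cxcl12, a chemokine that holds blood stem cells in their niche, stood at 52.1 ± 2.26 TPM, while Epo, the gene of erythropoietin, was at 0.621 and 0.970 TPM in replicates 1 and 2. The 11 genes of hypoxia and glycolysis summed to 2295 ± 323 TPM, led by Ldha, lactate dehydrogenase, at 1389 ± 278 TPM and the glucose transporter gene Slc2a1 at 326 ± 29.4 TPM. Immediate early and stress genes summed to 196 ± 4.72 TPM over 13 genes, with Dnajb1 at 67.1 ± 2.83 TPM and Fosb lowest at 0.0104 and 0.0103 TPM in replicates 1 and 2. The 5 sex-linked genes summed to 38.2 ± 1.85 TPM. Xist, transcribed from the inactive X chromosome, stood at 8.31 ± 0.510 TPM, and the Y-linked genes Eif2s3y and Ddx3y at 15.4 ± 0.0527 and 9.77 ± 1.21 TPM.

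The 2 preset histone lists differed in level. The 54 measured replication-dependent histone genes, whose transcripts normally end without a poly(A) tail, summed to 1669.8 ± 159 TPM (SD, n = 2), with a median of 7.5 TPM in replicate 1 and 8.39 TPM in replicate 2. Hist1h4d at 442 ± 48.3 TPM and Hist1h2bc at 237 ± 16.4 TPM were the highest. The 8 polyadenylated histone variants summed to 3903 ± 221 TPM, with H3f3a at 2021 ± 110.4 TPM and H2afz at 867 ± 73.4 TPM. The median proliferation gene, at 161 and 159.8 TPM, was 21.5-fold and 19.1-fold above the median replication-dependent histone gene in replicates 1 and 2. Hist1h2ap, outside that list but among the 20 highest genes, reached 3816 ± 531 TPM. This histone gene alone exceeded the sum of the 54 listed genes, so the sums describe the lists and not whole classes of histone genes. Of 4 noncoding RNAs without a tail, Rn7sk, which holds a transcription elongation factor inactive, stood at 105 ± 4.79 TPM, Rpph1, the RNA of ribonuclease P, at 61.0 ± 5.50 TPM, Rmrp at 2.24 ± 0.503 TPM and Terc, the telomerase RNA, at 0.497 and 0.0723 TPM in replicates 1 and 2. Rn7s1 and Rn7s2, 2 copies of the signal recognition particle RNA, reached 9185 ± 58.9 and 9184 ± 59.2 TPM. Histone paralogs and these 2 copies are nearly identical, so the split of reads within each family is uncertain.

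Among the other highest genes, Gpx1, an antioxidant enzyme, stood at 5766 ± 98.1 TPM, the metallothionein gene Mt1 at 5072 ± 368 TPM and the mitochondrial gene mt-Atp6 at 4728 ± 336 TPM (SD, n = 2). Gm28437, an unprocessed pseudogene on chromosome 1, reached 5103 ± 67.4 TPM. Whether its reads came from similar sequences elsewhere in the genome was not tested. Gm22133, annotated as a microRNA gene (chromosome 7, 45458089 to 45458197), reached 6838 ± 1254 TPM from 2406 and 2499 expected counts. It lies within Ftl1 (chromosome 7, 45457944 to 45459884), so its reads cannot be told from those of Ftl1, and its length of 109 nt leaves an effective length of 10 nt in the authors' scale, which inflates the TPM.

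Transcript tables gave the forms of genes with several promoters or splice variants. Of 6121 genes at 5 TPM or more in both libraries with at least 2 annotated transcripts, 5702 (93.2%) had the same leading transcript in both libraries. In the 419 genes that did not, the leading transcript held a median of 40% of the gene, against 75.2% in the others. Pklr, the pyruvate kinase gene of liver and red cells, was split between Pklr-201, which starts at the upstream, red cell promoter at 89136142 on chromosome 3 and held 45.2% ± 0.534 of the gene (SD, n = 2), and Pklr-202, which starts at the downstream, liver promoter at 89136572 and held 37.9% ± 2.23. For the nuclear receptor gene Hnf4a, Hnf4a-202, which starts at 163547187 on chromosome 2, held 94.0% ± 2.30, and Hnf4a-205, from the far upstream start at 163506808, held 5.43% ± 2.26. By posterior mean TPM the share of Hnf4a-202 was 75.5163%. Pkm-201 held 92.2% ± 0.101 of Pkm. Igf2-203 held 40.3% ± 0.451 of Igf2, and Fn1-202, annotated as a retained intron, held 33.0% ± 0.0246 of the fibronectin gene Fn1. Bcl2l1, a survival gene of maturing red cells, was led by Bcl2l1-201 with 62.2% ± 6.16 and Bcl2l1-202 with 28.1% ± 5.90, the former from 152831728 and the latter from 152830666 on the minus strand of chromosome 2. The 10 highest list genes whose leading 2 transcripts each held at least 20% included Hbb-bs, led by Hbb-bs-202 (63.6% ± 1.34). Trf, Fga and Apoa2 were also among them, led by Trf-201 (64.0% ± 0.377), Fga-201 (73.5% ± 0.377) and Apoa2-201 (62.5% ± 0.587). Their second transcripts were Trf-209 (23.4% ± 2.94), Fga-202 (26.5% ± 0.377) and Apoa2-204 (32.2% ± 2.35). Another, Serpinc1, was split between Serpinc1-204 (49.1% ± 0.443) and Serpinc1-205 (48.9% ± 0.458). Hbb-bs-202 and Trf-209 are annotated as retained introns, and Serpinc1-204 as subject to nonsense-mediated decay. Shares of transcripts that overlap are estimates of the authors' quantification and carry its uncertainty beside the SD.

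Replicate 2 was then compared with replicate 1, which asks how far 2 pools of the same stage differ. Most genes lay close together. Across 13066 genes at 1 TPM or more in either library, Pearson's r of log2(TPM + 1) was 0.988 and Spearman's rho 0.987. These are correlations across genes, which are not independent replicates. Of 8781 genes at 5 TPM or more in either library, 84.9% differed by less than 1.2-fold and 59 by more than 2-fold, 36 of them higher in replicate 1 and 23 higher in replicate 2. Of these 59, 24 were protein-coding and 16 pseudogenes. The exact 95% counting interval lay wholly beyond 2-fold for 31 genes. The count of genes beyond 2-fold was 31 with counts scaled by TMM, 31 by the median of ratios and 36 by spike-ins, and 229 without the filter on low values. The scaled counts + 1 took the place of TPM + 1, so the measure changed as well as the scale. The counts differed by more than sampling noise (chi-square 317605 on 17601 degrees of freedom), so they are not copies of a single library. Libraries made separately from the same RNA can differ so too, and that the pools are separate replicates rests on the labels. With 1 library on each side, the differences have no replicate check, intervals cover counting error only, and no p-value is given for a gene.

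**Figure D2:**
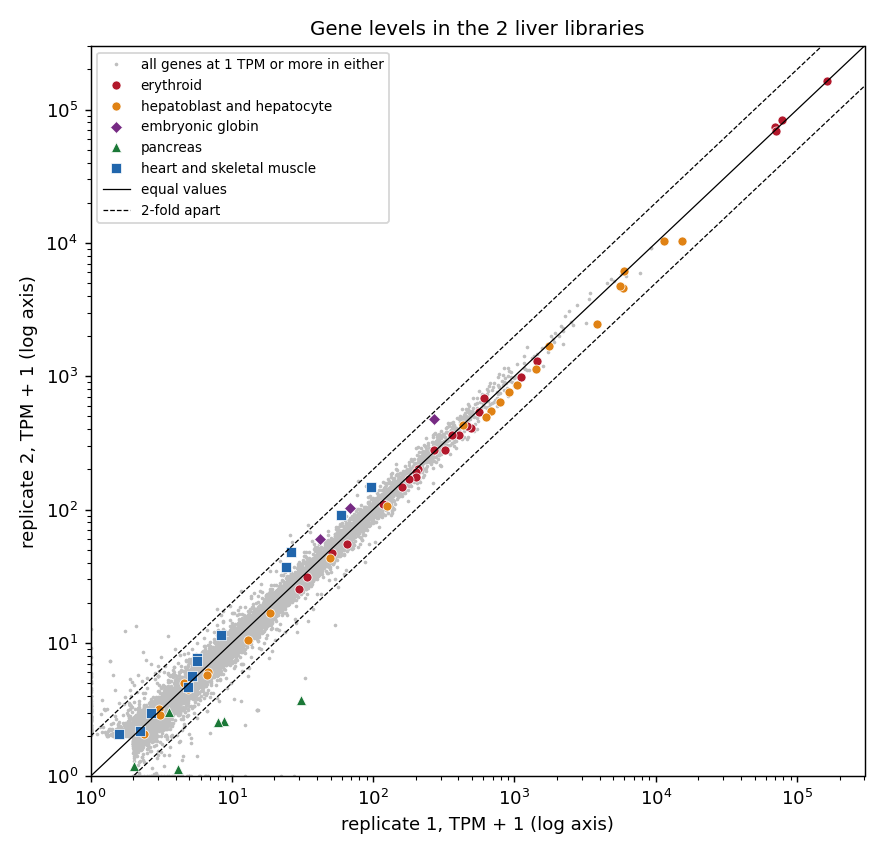
TPM + 1 of each gene in replicate 1 (horizontal log axis) against replicate 2 (vertical log axis), with genes at 1 TPM or more in either library in grey, 5 preset lists in colour, a solid line at equal values and broken lines at 2-fold differences. Erythroid genes follow the solid line, pancreas genes such as Ctrb1 (30.1 and 2.73 TPM) lie below the line, and embryonic globins such as Hbb-y (268 and 477 TPM) above it.

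Genes for digestive proteins of the pancreas made up 6 of the 8 genes most in excess in replicate 1, among genes with at least 10 TPM and 50 expected counts and without pseudogenes. Ctrb1, a chymotrypsinogen gene (ENSMUSG00000031957; chromosome 8, 111686519 to 111691010), stood at 30.1 and 2.73 TPM in replicates 1 and 2, a log2 ratio of -3.06 (95% counting interval -3.74 to -3.10). The ratio is of TPM + 1, which draws ratios of low genes toward 0, while the interval is of the counts alone. Clps, the gene of colipase, stood at 31.8 and 4.44 TPM and had a log2 ratio of -2.59 (95% counting interval -3.14 to -2.44). The amylase copies Amy2a2, Amy2a3, Amy2a4 and Amy2a5, which are nearly identical and share their reads, each had a log2 ratio between -2.30 and -2.28. By posterior mean TPM the copies ran from -2.81 for Amy2a2 to -1.61 for Amy2a4. The other 2 of the 8 genes most in excess were mt-Nd4l, a mitochondrial gene that overlaps its neighbour, with a log2 ratio of -1.98, and Gm17134, an antisense gene, with -1.67. In the preset lists, Spp1 of the bile duct (17.3 and 6.74 TPM), Fbp1 of gluconeogenesis (86.1 and 39.7 TPM), Cps1 of the urea cycle (27.4 and 13.7 TPM), Cyp8b1 of bile acid synthesis (8.85 and 4.04 TPM) and the transporter Slco1b2 (5.96 and 2.91 TPM) were the members of their lists furthest apart, and each was higher in replicate 1. Eosinophil and muscle genes were among the 8 most in excess in replicate 2 by the same rule. Prg2, which encodes the major basic protein of eosinophil granules (chromosome 2, 84980461 to 84983632), stood at 24.7 and 63.3 TPM in replicates 1 and 2, a log2 ratio of 1.32 (95% counting interval 1.27 to 1.55), and the eosinophil ribonuclease gene Ear6 had 0.91. Myl1, Sln and Tnnc2, which encode proteins of skeletal muscle fibres, had log2 ratios of 0.93, 0.90 and 0.88. The histone gene Hist1h2ai was 2.29-fold and Rpl9-ps6, annotated as protein-coding and a copy of a ribosomal protein gene, 2.03-fold higher in replicate 2. Lbhd1 completed the 8 with a log2 ratio of 0.91 by TPM, but its counts gave an interval of 0.13 to 0.40.

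Whole lists differed between the libraries by less than most of these single genes. There were 30 lists with at least 5 members at a mean of 1 TPM or more. Of these, 17 had a median log2 ratio outside the central 95% of 10000 random lists of the same size and expression. Chance gives 1.5 for genes that vary independently, but members of a list can vary together. Of the 17 lists, 15 were lower and 2 higher in replicate 2 than their random lists. Hepatocyte lists were among the lower. The hepatoblast and hepatocyte list had a median log2 ratio of -0.22, with 22 of 25 members higher in replicate 1. Ahsg moved furthest (3806 and 2463 TPM in replicates 1 and 2), and Trf stood at 15233 and 10336 TPM. The medians were -0.28 for coagulation, -0.33 for complement, -0.21 for lipoprotein assembly, -0.22 for iron handling, -0.31 for the urea cycle, -0.42 for gluconeogenesis and amino acid breakdown and -0.36 for cytochrome P450 genes. The cytochrome P450 median rests on 5 members, 3 higher in replicate 1 and 2 higher in replicate 2. These lists share some members. The same held for the pancreas list (-1.76), the bile duct list (-0.50), the B lymphoid list (-0.33), the macrophage list (-0.18), the megakaryocyte and platelet list (-0.17) and the endothelial list (-0.17), in which all 16 members were higher in replicate 1. The pancreas and bile duct medians rest on 5 members each and the B lymphoid median on 7, none at 10 TPM or more in both libraries. The urea cycle and gluconeogenesis medians rest on 6 members each. The erythroid list had a median of -0.11, with 19 of 25 members higher in replicate 1, although its sum was higher in replicate 2 (388031 and 395909 TPM in replicates 1 and 2), where Hbb-bs and Hbb-bt were higher. Heart and skeletal muscle genes (0.45, 9 of 11 members higher in replicate 2) and replication-dependent histone genes (0.22, 33 of 48 members) lay above their random lists. With the length trend removed the histone median was 0.07 and the hepatocyte median -0.13, both still outside. The other 13 lists, proliferation (0.01), heme synthesis (-0.06) and granulocyte and monocyte genes (0.05) among them, lay within the central 95%, with medians from -0.15 for bile acid and drug transport to 0.14 for the mesothelial list. Positions are relative to other genes, and the sizes printed above are not fixed. The median of all genes was -0.05 by TPM + 1. By scaled counts + 1 it was -0.00074 with TMM scaling and 0.12 with spike-in scaling. The medians that follow are of counts, so they differ from those above by measure as well as by spike-in scaling. Under it the medians were -0.07 for the hepatoblast and hepatocyte list, -0.10 for coagulation, -0.09 for complement, -0.0014 for lipoprotein assembly, -0.03 for iron handling, -0.14 for the urea cycle, -0.28 for the bile duct list, -0.13 for the B lymphoid list, -0.01 for the macrophage list, -0.00091 for the megakaryocyte and platelet list and 0.36 for histone genes. Those of the erythroid list (0.08) and the endothelial list (0.02) were above 0. With this scaling all 17 lists stayed outside the central 95% of their random lists, each on the same side. A common factor moves a list and its random lists almost alike, so the scale itself could hardly change this. With the length trend removed the erythroid and endothelial lists had medians of -0.06 and -0.10 and lay within the central 95% (6.24 and 3.45 percentile), as did the megakaryocyte and platelet list with the GC trend removed (median -0.06, 7.5 percentile).

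**Figure D3:**
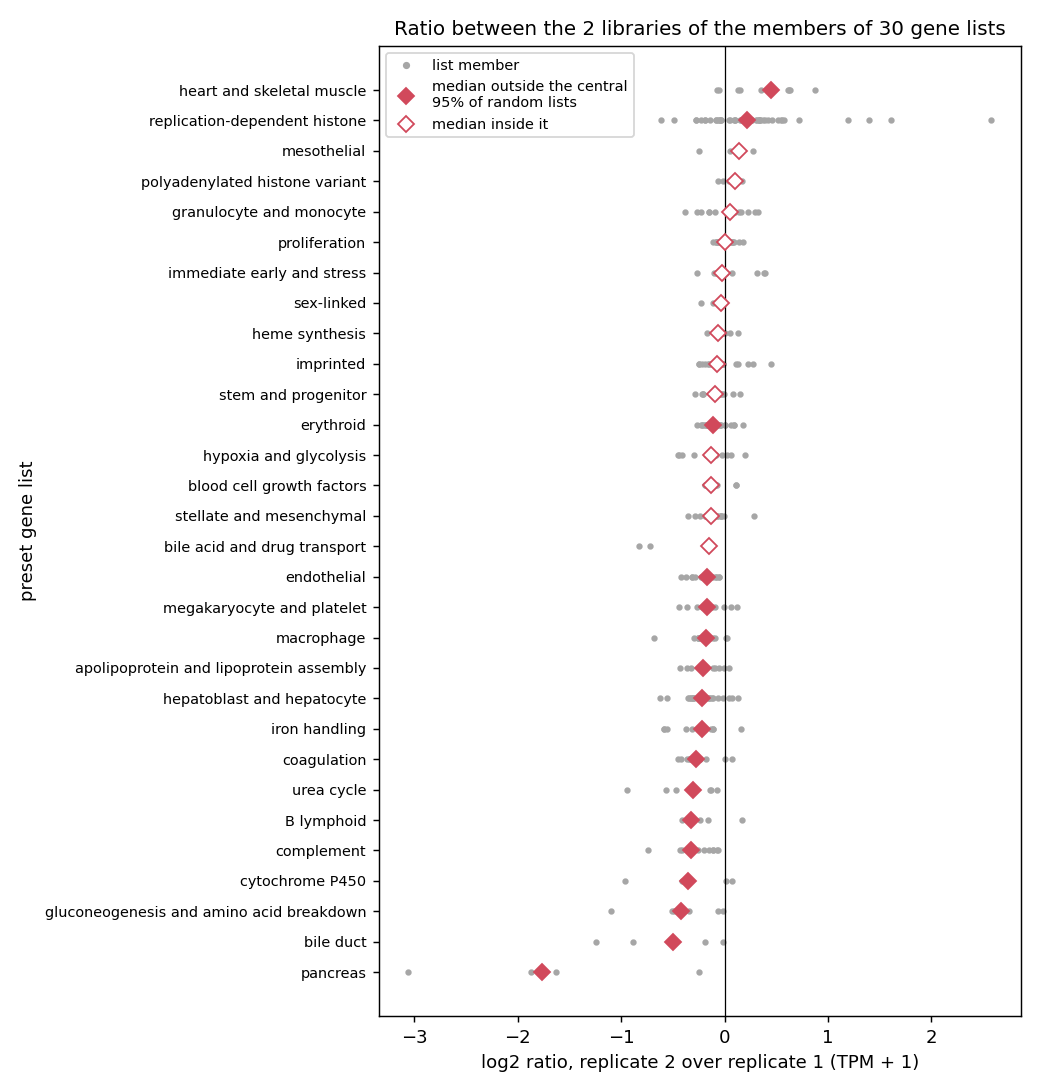
Log2 ratio of TPM + 1, replicate 2 over replicate 1 (horizontal axis), for the members of 30 preset lists in grey and their medians as diamonds, filled where the median lies outside the central 95% of 10000 random lists matched on expression. Medians run from -1.76 for the pancreas list to 0.45 for the heart and skeletal muscle list.

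Spike-in RNAs took 2.24% of expected counts in replicate 1 and 2.03% in replicate 2. Across 47 spike-ins with at least 50 counts in each library, Pearson's r of log2 counts was 0.997 and Spearman's rho 0.993. For 28 of the 47 the 95% counting interval of the ratio excluded that of the summed spike-ins, so these also differed by more than sampling noise. Among spike-ins with more than 1000 counts in replicate 1, the SD of the log2 ratio was 0.23 (22 spike-ins), against 0.17 for 5292 genes above the same count. The spike-in ratios are of counts, and those of genes are of TPM + 1 for genes at 5 TPM or more. The 2 SDs are therefore of unlike measures and do not show which group varied more. The spread between the libraries was smaller at greater depth: the SD of the log2 ratio was 0.41 for genes with 50 to 200 expected counts in replicate 1 and 0.17 for those above 5000.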

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

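Signal appeared in entries that no comparison used. The gene tables hold 26248 entries with a numeric identifier and no symbol, and these summed to 14.96 expected counts in replicate 1 and 24.94 in replicate 2. Most of this came from a single entry, the same in both libraries, with 12 and 18 counts, above the 3 that a count of 0 allows. Only 4 and 5 entries had any counts. The labels do not say what these entries are, and no explanation was tested.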

How the results depend on the processing

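The direction of the erythroid to hepatocyte ratio depended on the genes summed: without the 4 adult globins and without Alb, Afp and Apoa1 its log2 value was -2.03, with shares of 0.714% and 2.93%. This set left Trf and Apoa2, 2 of the 4 highest hepatocyte genes, in place. Without the 4 highest genes of each list, chosen after seeing the data, the value was -1.12 and the hepatocyte share 1.56%. Both reversals follow from leaving out the adult globins. By expected counts the ratio was 1.44, the shares 19.5% and 7.20%, and the embryonic alpha-like share 0.0514%, since long transcripts weigh more in counts. Without mitochondrial genes in the total the erythroid share was 40.0002%. Genes beyond 2-fold numbered 229 with no filter, 31 with TMM or median-of-ratios scaling, 36 with spike-in scaling and 31 by counting intervals, the last chosen after seeing the data as an alternative. These scalings also took scaled counts + 1 in place of TPM + 1. TMM factors of 1.004 and 0.996 in replicates 1 and 2 moved ratios little, so the lower TMM number came with the change of measure. The causes were not tested further. Pearson's r between libraries was 0.966 with a pseudocount of 0.1, 0.995 with no filter and 0.992 by posterior mean. The cause was not tested. The same leading transcript was found in 96.4% of genes at 50 TPM or more and in 98.8% where it held at least 50% of the gene. Spike-ins took 3.29% of TPM. With each library alone, detected genes ran from 12656 to 12741, the erythroid share from 38.8 to 39.6%, the hepatocyte share from 4.53 to 5.57%, the log2 ratio from 2.80 to 3.13, the embryonic beta-like share from 0.209 to 0.341%, the alpha-like share from 0.0291 to 0.0440% and the spike-in share from 2.03 to 2.24%. Lists standing apart numbered 16 to 19 under 7 alternatives. Of these, median-of-ratios scaling, posterior mean TPM and removal of the length or GC trend were chosen after seeing the data, as were all alternatives for single genes. Also chosen then, genes beyond 2-fold numbered 44 by posterior mean, 43 without pseudogenes and 49 without the length trend and 57 without the GC trend, and the shares were tried without features under 200 nt. Of 210 list values 196 kept their side of the threshold, 3 fell inside (erythroid and endothelial without the length trend, megakaryocyte and platelet without the GC trend) and 11 moved outside (stellate, mesothelial and hypoxia lists). TMM, median-of-ratios and spike-in scaling differ from each other by a common factor. Such a factor moves a list and its random lists almost alike, so these settings are not separate checks of the lists. All 80 values of single genes kept their sign, but some lay outside the gene's counting interval, such as Ctrb1 at -2.89 with TMM scaling, and mt-Nd4l stood at -1.52 with spike-in scaling and at -1.41 by posterior mean. No paired analysis was possible because the 2 libraries are a single group. Depth limits genes with few counts, where the spread was widest.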

Other observations

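The lists of eosinophil, exocrine pancreas and skeletal muscle genes, and the tests in the last 2 paragraphs, were chosen after the values were seen. So were the tests of length or GC bias as the whole cause and of sampling in part of the genes. The tests on pancreas and muscle genes were set a second time after the first outcome, and that on muscle a further time, with each version given. The other tests were set before.

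Eosinophil genes were higher in replicate 2. The list of 10 summed to 54.7 and 116 TPM in replicates 1 and 2, and 6 of its 7 members at a mean of 1 TPM or more were higher in replicate 2, with a median log2 ratio of 0.91. Prg3, a homolog of the granule protein gene Prg2, stood at 1.67 and 5.98 TPM and Epx, the eosinophil peroxidase gene, at 1.13 and 3.31 TPM, while the surface receptor gene Siglecf stood at 1.68 and 1.67 TPM and Ear10 had a count of 0 in both. The list was drawn up because Prg2 and Ear6 stood out, so it is not independent evidence of direction. Exocrine pancreas genes, 15 measured, summed to 75.6 and 20.5 TPM, and 17 skeletal muscle genes to 292 and 423 TPM in replicates 1 and 2. These lists were also drawn up from what stood out in these libraries.

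RNAs that lack a poly(A) tail were unequal in libraries labelled total RNA. The median proliferation gene lay 21.5-fold and 19.1-fold above the median replication-dependent histone gene, beyond the 10-fold set in advance, so cDNA made mainly from polyadenylated RNA may explain the low median of that list. It would not by itself give the level of Hist1h2ap, a histone gene outside the list at 3816 ± 531 TPM. Of the 3 untailed noncoding RNAs set in advance, Rmrp was as low as 1.89 TPM and Rn7sk as high as 108 TPM, and Rn7s1 stood at 9185 ± 58.9 TPM, so a complete loss of such RNAs is argued against while a lower yield stays open. Division of reads among near-identical histone copies and biological explanations were not tested.

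A set of 59 genes lay over 2-fold apart between the libraries. A different sex ratio of the pools is argued against by a log2 ratio of -0.11 for Xist and a median of -0.03 for Y-linked genes, and length bias as the whole cause by 49 of the 59 genes that stayed beyond 2-fold after its trend was removed, as did 55 after the GC trend was. Both biases may contribute, since the log2 ratio correlated across genes with length (Spearman's rho -0.246) and with GC content (-0.358), and with length across spike-ins (-0.418). The 2 trends were not removed together. Division of reads among similar sequences was not tested for this set, which held 16 pseudogenes, 12 of them higher in replicate 2. The set also held genes with the same expected counts. Amy2a2, Amy2a3 and Amy2a4 each had 712.22 and 143.45 in replicates 1 and 2. The small nuclear RNA genes Gm23444 and Gm23472 each had 1.11 and 24.23. Such genes do not count as separate differences. Counting intervals take the expected counts, which are estimates, as reads and do not cover that division. Within this limit, sampling of few reads as the cause of the whole set is argued against. The share that follows and its exact interval take the 59 genes as independent, which they are not. The counting intervals of Amy2a2, Amy2a3, Amy2a4, Gm23444 and Gm23472 all lay wholly beyond 2-fold. Taking each set of equal counts as a single gene would lower the share, and the exact interval is too narrow. The counting interval of 52.5% of the 59 genes lay wholly beyond 2-fold (exact 95% interval 39.1 to 65.7%), against under 10% set in advance. Of the other 28 genes, 10 exclude equal levels even by intervals widened for all 8781 genes compared, so sampling is argued against as the cause of their whole difference, as it is for Nckipsd, named after its values were seen, where 375 and 423 counts do not give a log2 TPM ratio of -1.01 and the estimated length differed (1559 and 2898 nt), and it stays open for the other 17, of which 12 include equal levels at 95%.

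Gene lists of liver, pancreas and muscle stood apart between the libraries. More skeletal muscle RNA in library 2 may explain the muscle genes. Tests on 16 and 17 added genes (medians 0.68 by TPM + 1 and 0.78 by counts) decide nothing, since they held genes that had prompted the list. The 15 others, 1 of them in another list, had a median log2 count ratio of 0.78. The most abundant, Mylpf and Tnnc1, stood at 63.4 and 76.8 TPM and 61.8 and 61.4 TPM in replicates 1 and 2. These 15 genes come from the same 2 libraries and can vary together with the genes that prompted the list. They are therefore not independent support. For more pancreas RNA in library 1, the first test had 4 genes (median log2 ratio of TPM + 1 of -1.08), too few to decide. A second was then set on 9 genes with at least 10 counts, of which 8 were higher in replicate 1 (median log2 count ratio of -2.30). Both left out the genes counted above as over 2-fold apart. The 2 medians are of unlike measures and cannot be set side by side. A trend with length alone or GC content alone as the whole cause of lower hepatocyte genes is argued against by a median of -0.16 after the GC trend and -0.13 after the length trend was removed. Each was smaller in size than the -0.22 before removal. The 2 trends were not removed together, so their joint effect was not tested. An equally lower share for all hepatocyte genes stays open, as the SD of their log2 ratios was 0.22 over 58 genes, against a median of 0.19 in random lists.

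Further hypotheses on the same genes were tested and left undecided. That metabolic genes were lower by more than secreted-protein genes in replicate 2 was the first reading of the lists. Their median log2 ratios were -0.15 for 18 metabolic and -0.27 for 38 secreted-protein genes. The difference of 0.12 was in the other direction, with a bootstrap 95% interval of -0.27 to 0.20 that decides neither. The pattern was then reworded, and a test of a length or GC trend in that difference was dropped. An earlier developmental state of the pool behind library 2 had the embryonic globins higher, by at least 0.52 on the log2 scale, but not the lower granulocyte genes it called for (median 0.05), and stays open.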
